A study of Mus musculus with 6 samples.

How the data were processed

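Total RNA from mammary fat pads 4 and 9 of 6 female mice was extracted with a kit for lipid-rich tissue, labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols. The authors deposited a table of intensities on a linear scale for these 6 arrays, with 45037 probe sets and no control probe sets. How probe-level signals were summarised and scaled is not given in the sources used here. Array medians lay between 98.5 and 105 before any scaling here, and 690 to 815 values per array were listed at exactly 1. Groups were taken from the genotype in the labels, with 3 WT and 3 Pxmp2-/- mice, and replicate numbers from the sample titles. There were 0 columns left unmatched to a sample, and none of the columns were identical. Arrays with the same number in both groups did not deviate together, so the replicate numbers were not taken to pair mice.

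Intensities were used as deposited and transformed to log2(intensity + 16), the pseudocount damping the noise of dim probe sets. Probe sets with a mean log2 level above the 40th percentile (6.23, or an intensity of 59.1) were tested, which left 27022. Gene names came from the platform annotation, which gave a single symbol for 34945 probe sets, several for 932 and none for 9160. Symbols were looked up by Entrez number in a RefSeq gene table of the assembly GRCm38.p6, which changed 0 of them, and 204 of the single-symbol probe sets had no match there. Probe sets with several symbols were left unnamed. The files name no genome build, so that table served for names, chromosomes and gene order, and no coordinates are given.

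Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Pxmp2-/- minus WT, two-sided), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Standard errors are the moderated ones of limma, and SDs are of intensities over the 3 mice of a group. For tests by gene, the probe set with the highest mean log2 level stood for each gene. The named genes were Pxmp2 and, per direction, up to 12 genes with the largest change among single-symbol probe sets past the threshold whose groups did not overlap. Places left open went to the genes with the next smallest p, and the probe set with the smallest p was used for each. Genes named within a list were those with the smallest p in it or known markers of the tissue, the latter chosen after the data were seen.

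There were 31 gene lists, fixed before the data were examined, for peroxisome and lipid pathways, hormone and growth factor genes, cell types, tissue handling and the neighbours of Pxmp2. The 30 lists with at least 5 tested genes were tested with camera in limma, which compares a list with all other genes, at a preset correlation of 0.01 and with Benjamini-Hochberg adjustment over the lists. The same test with the correlation estimated for each list, and the rotation test fry, were alternatives. Counts adjusted over the list alone use Benjamini-Hochberg within a list. A list of MHC class II genes was written after the calls had been seen.

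The procedure was tested on simulated data with the real means and spreads of the 27022 probe sets, in 5 runs with 200 changed probe sets each. At the adjusted threshold 51.9% of changes of 1.5-fold, 95.5% of 2-fold and 99.7% of 3-fold were called, with 7.6 unchanged probe sets called per run. These shares hold for 200 changes. With the 17 calls of the real data a smaller p is needed to pass, so the shares are likely lower there. Differences above 2-fold that did not pass included Pcgf5 (log2 difference -1.31) and Egfr (-1.11). In 20 simulated runs with the endothelium list lowered by 0.2 log2 and members independent, camera called it in 20 runs, and in 4 with an estimated correlation, and 2 of 580 unchanged lists were called. In the real data the estimated correlation within a list was 0.64 for macrophage and 0.63 for interferon response genes, against 0.09 for endothelium. Splits of the real arrays that mixed the genotypes had 3 to 12 lists called each. The share of false calls in the simulation therefore does not carry over to the real lists.

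Alternatives were quantile normalization, median centring, pseudocounts of 1 and 64, no level filter or the 60th percentile, a mean-variance trend, array weights, tests by gene, the replicate number as a block and removal of probe sets ending in _x_at or _s_at. Thresholds of 1.5-fold and of 0.10, and leaving out each array in turn, were also run. Leaving out an array kept the probe sets tested on all 6. Plots were drawn with matplotlib 3.10.9.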

Results

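RNA of mammary fat pads 4 and 9 was hybridised to Affymetrix arrays, with 3 mice lacking Pxmp2 and 3 wild-type (WT) mice, all females of the C57BL/6J background. Pxmp2 is a channel protein of the peroxisomal membrane, and the study asked whether it is needed for the growth of the mammary epithelium. Ovaries were removed at 21 days of age, estradiol was injected at 31 days so that puberty started at a common time, and the tissue was taken 8 h later. Each array gave intensities for 45037 probe sets, with medians between 98.5 and 105 arbitrary units. The upper quartiles lay between 455 and 469 in WT mice and between 428 and 448 in Pxmp2-/- mice. Of the probe sets, 34945 carried a single gene symbol, 932 carried several and 9160 none, and those with several or none are unnamed here. The 27022 probe sets above the level filter covered 12775 named genes. Correlations across all 45037 probe sets, which are not independent replicates, were 0.989 to 0.991 within groups and 0.986 to 0.988 between groups. The first principal component of the 27022 probe sets held 40.4% of the variance and placed the 3 WT arrays on one side of the 3 Pxmp2-/- arrays. On the second component (18.5%) Pxmp2-/- 1 stood apart at 26.7, with the other arrays between -15.7 and 6.6. The number of arrays, 3 per genotype, limits the precision of every value.

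Pxmp2 itself was the most strongly lowered transcript. Its probe set (1417841_at) read 2635 ± 166 (SD, n = 3) in WT mice and 277 ± 27.3 (SD, n = 3) in Pxmp2-/- mice. The log2 difference was -3.18 ± 0.10 (SE), or 9.07-fold, with a limma adjusted p of 6.14e-05. The single WT mice read 2643, 2465 and 2797, and the single Pxmp2-/- mice read 308, 262 and 260, so every label matched its genotype. Where this probe set lies relative to the disrupted part of the gene is not given in the sources used here. Fold changes here and below are on the log2(intensity + 16) scale, which understates the change of dim transcripts.

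Beyond Pxmp2, few transcripts passed the threshold. At an adjusted p under 0.05, 17 probe sets differed, that of Pxmp2 included, 7 higher and 10 lower in Pxmp2-/- mice. They included 14 probe sets of 13 named genes, and 3 unnamed probe sets (1430196_at, 1450803_at and 1430392_at) that were all lower, at log2 differences of -1.32, -0.93 and -0.96. Of the 13 named genes, 9 lie on chromosome 5, Pxmp2 itself among them. Without Pxmp2, 8 lie on chromosome 5 and 4 elsewhere. Genotypes were fully separated in 22.8% of tested probe sets, and 4497 had an unadjusted p under 0.05. By chance 10% and 1351 would be expected on average. The 9 other ways to split the 6 arrays into 3 and 3 gave 5.84% to 17% and 612 to 2822 probe sets. A probe set without ties separates fully in only 1 of the 10 splits, so these shares depend on the real one. The other splits also mix the genotypes and hold any genotype difference as spread. They therefore do not show how far chance counts vary. Among those 4497, 1655 were higher and 2842 lower. After quantile normalization 2130 were higher and 2128 lower at this p, and after median centring 1472 and 3333.

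The named genes with a probe set that was higher past the threshold were Uba6, Hsd17b11, H2-Ab1, 2610524H06Rik, Clasp2 and Naaa. The probe set of Uba6, an enzyme that activates ubiquitin, rose from 166 ± 23.2 to 419 ± 11.7 (SD, n = 3 each), a log2 difference of 1.27 ± 0.11 (SE) with an adjusted p of 0.0249. That of Hsd17b11, a dehydrogenase of lipid droplets, rose by 1.05 ± 0.09. H2-Ab1, the beta chain of an MHC class II molecule, rose from 291 ± 2.36 to 598 ± 22.7, a log2 difference of 1.00 ± 0.08 with an adjusted p of 0.0193. The uncharacterised gene 2610524H06Rik rose by 0.98, Clasp2, which binds growing microtubule ends, by 0.97, and Naaa, a lysosomal acid amidase, by 0.78. The next genes by rank did not pass. They were the lysozyme gene Lyz2 with a log2 difference of 0.85 (adjusted p = 0.0589), Cox18 with 0.65, the calcification inhibitor Mgp with 0.82, H2-Aa with 0.89, Pip5k1a with 0.70 and H2-Eb1 with 0.84 (adjusted p = 0.109).

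Beside Pxmp2, the named genes with a probe set that was lower past the threshold were Dynll1, Fst, Zfp932, Tmem158, Eif4h and Pebp1. Fst encodes follistatin, which binds activin. It fell from 506 ± 39.1 to 214 ± 27.1 (SD, n = 3 each), a log2 difference of -1.19 ± 0.11 (SE) with an adjusted p of 0.0274. The dynein light chain gene Dynll1 differed by -1.43 ± 0.11, the zinc finger gene Zfp932 by -1.08 ± 0.10, and Tmem158 by -0.99 ± 0.11. The translation factor gene Eif4h differed by -0.95 ± 0.09, and Pebp1, an inhibitor of Raf kinase, by -0.89 ± 0.09. Not past the threshold were the basement membrane collagen gene Col4a4 with -0.81, Sh3rf1 with -0.70, the Polycomb gene Pcgf5 with -1.31, the epidermal growth factor receptor gene Egfr with -1.11 (adjusted p = 0.0846) and D130051D11Rik with -0.69.

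The probe set past the threshold was the dimmest tested one of its gene for Dynll1, Eif4h, Hsd17b11, Pebp1, Clasp2 and Uba6. That probe set read 158 in WT mice for Eif4h and 117 for Dynll1, whose brightest probe sets read 7270 and 5283. For H2-Ab1, 2 probe sets passed, the dimmest and a brighter one. The brighter one rose from 521 in WT to 979 in Pxmp2-/- mice (limma adjusted p = 0.0274). For several genes, other probe sets did not follow the named one. The other probe sets of Dynll1 differed by -0.16, -0.05 and -0.00467, those of Eif4h by between -0.04 and 0.02, that of Hsd17b11 by 0.02 and that of Pebp1 by -0.09. For Clasp2 they differed by -0.63 and -0.03, for Pip5k1a by 0.12 and -0.08, and for Sh3rf1 by 0.11, 0.10 and -0.05. The other probe sets of Uba6 were higher too, with separate groups but by less, at 0.25 and 0.22 (limma adjusted p = 0.23 and 0.308). In contrast, all 3 probe sets of H2-Ab1 were higher (1.00, 0.89 and 0.56), as were all 4 of H2-Aa (0.89, 0.80, 0.77 and 0.66), and both of Fst were lower (-1.19 and -0.87). Naaa was higher in a further probe set (0.71) and nearly level in another (0.10), while Egfr was lower in 2 probe sets (-1.11 and -0.95) and slightly higher in 2 (0.13 and 0.14). Pcgf5 had 2 dimmer probe sets at 0.22 and 0.08, and Col4a4 had another at -0.32.

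The number of calls depended on single arrays and on the filter. Without WT 1, 2 or 3 it was 6, 2 or 1, and without Pxmp2-/- 1, 2 or 3 it was 33, 1 or 1. With no level filter it was 1. Pxmp2 passed in each of these fits, and all 17 probe sets kept their direction in them.

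**Figure D1:**
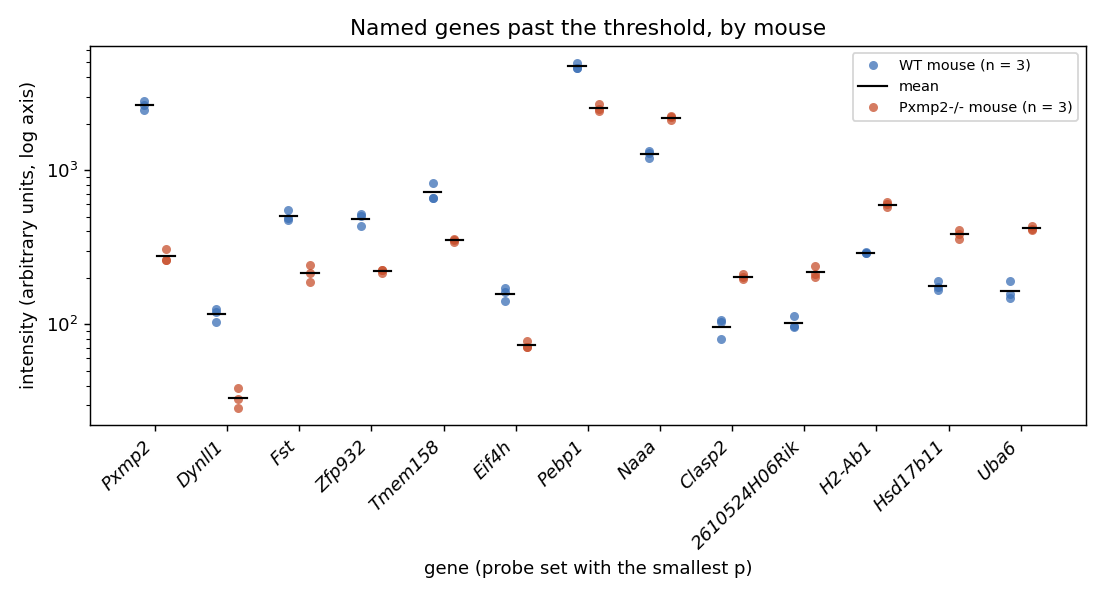
Intensity (log axis, arbitrary units) of the 13 named genes past the threshold, each point a mouse (3 WT in blue, 3 Pxmp2-/- in red) and each bar a group mean. Pxmp2 lay between 2465 and 2797 in WT mice and between 260 and 308 in Pxmp2-/- mice. Only genes whose groups did not overlap were chosen for naming, so none of those shown overlap.

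Peroxisomal transcripts other than Pxmp2 differed little between genotypes. Among 26 tested genes of peroxisome biogenesis and membrane, Pxmp2 alone passed over all probe sets and adjusted over the list alone. The tetraspan membrane protein gene Pxmp4 differed by -0.32 ± 0.09 and the division factor gene Pex11g by -0.34 ± 0.11 (log2, SE), both with a limma adjusted p of 0.111 when adjusted over the list alone. The import receptor gene Pex5 differed by 0.03. The list averaged -0.17 log2 with a camera adjusted p of 0.364, and -0.048 without Pxmp2, a choice made after the data were seen. Genes of peroxisomal fatty acid and ether lipid metabolism rose slightly as a list, by 0.071 on average (camera adjusted p = 0.0213), and the adjusted p was 0.51 with an estimated correlation. None of its 30 tested genes passed over all probe sets or adjusted over the list alone. Its largest values were Slc27a2, a very long chain acyl-CoA synthetase, with 0.64 ± 0.18, Decr2 with 0.45 ± 0.13 and Acox3 with 0.37 ± 0.11. The list's call was lost without WT 2 (0.061, adjusted p = 0.064) and without Pxmp2-/- 2 (0.068, adjusted p = 0.05). It was also lost with fry (adjusted p = 0.13) and without chromosome 5 genes, Acox3 among them (0.062, adjusted p = 0.05).

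Other lipid and redox lists did not pass the camera threshold on all 6 arrays, and none of their genes passed over all probe sets or adjusted over the list alone. Leaving out WT 3 made cholesterol synthesis (-0.15, adjusted p = 0.027) and the prostaglandin and leukotriene pathway (0.082, adjusted p = 0.032) pass, and leaving out Pxmp2-/- 1 did so for mitochondrial fatty acid oxidation (0.059, adjusted p = 0.032). PPAR target genes averaged 0.034 over 24 tested genes (camera adjusted p = 0.378), with Pdk4, which restrains glucose oxidation, at 0.39 ± 0.18 and Acot2 at -0.26 ± 0.11. Over the fits without single arrays this mean ranged from -0.038 (without WT 1) to 0.09 (without WT 3). Mitochondrial fatty acid oxidation averaged 0.03 over 19 genes (adjusted p = 0.209), with Acads at -0.33 and Etfdh at 0.29, and turned to -0.0051 without WT 1. Fatty acid and triglyceride synthesis averaged -0.05 over 30 genes (adjusted p = 0.732), with Elovl1 at -0.20 and Acacb, which makes malonyl-CoA, at -0.19, and moved to -0.028 without WT 1 and to -0.076 without WT 3. LXR target genes averaged 0.025 over 12 genes (adjusted p = 0.495), with a median of -0.014 and with Pltp at 0.30 and Lpcat3 at 0.28. That mean was 0.0048 without Pxmp2-/- 1 and 0.047 without Pxmp2-/- 2. Cholesterol synthesis averaged -0.047 over 20 genes (adjusted p = 0.821) and turned to 0.0022 after quantile normalization, with Insig1, a brake on sterol synthesis, at -0.22 and Stard4 at -0.24. It was also positive without WT 1, WT 2 or Pxmp2-/- 2 (0.005, 0.0045 and 0.0078). Antioxidant enzymes averaged -0.0092 over 26 genes, against the upward direction of camera (adjusted p = 0.523), turned to 0.023 after quantile normalization, and ranged from -0.04 without WT 1 to 0.011 without WT 2. Heme oxygenase (Hmox1) differed by 0.28 and Nqo1 by -0.22. Catalase (Cat), the peroxide-splitting enzyme of peroxisomes, read 12600 ± 1277 in WT and 13334 ± 892 in Pxmp2-/- mice (SD, n = 3 each). The prostaglandin and leukotriene pathway averaged 0.053 over 18 genes (adjusted p = 0.107), with the receptor gene Ptgfr at 0.38 and the prostacyclin synthase gene Ptgis at -0.43, and was 0.034 without WT 1.

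Mammary epithelial transcripts were mostly dim in these fat pads. Of 33 luminal genes on the array, 12 were above the level filter, and of 19 basal genes, 8. The luminal list averaged 0.11 (camera adjusted p = 0.355), and none of its genes passed over all probe sets or adjusted over the list alone. This mean was 0.071 without Pxmp2-/- 1 and 0.17 without WT 1. The epithelial cadherin gene Cdh1 read 65.9 ± 44.3 in WT and 140 ± 51.7 in Pxmp2-/- mice (SD, n = 3 each), and the milk protein gene Lalba 74.1 ± 15.5 and 102 ± 4.59. The basal list had a mean of -0.035 and a median of 0.15, with an upward camera direction (adjusted p = 0.41). The transcription factor gene Snai2 was lower at -0.80 ± 0.21, and was the single basal gene to pass adjusted over the list alone, while Trp63 differed by -0.56 ± 0.24. Snai2 was not dim, at 867 ± 152 in WT and 500 ± 148 in Pxmp2-/- mice (SD, n = 3 each), where Trp63 read 194 ± 28.1 and 131 ± 48.5. In which cells of the pad Snai2 fell was not tested. Without WT 1 or Pxmp2-/- 2 the basal mean turned to 0.021 or 0.006, and without WT 3 or Pxmp2-/- 1 it was -0.1 or -0.077.

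Estrogen-responsive genes showed no common shift 8 h after estradiol, with a mean of 9e-04 over 24 tested genes (camera adjusted p = 0.228). This mean turned to -0.0082 after median centring, and was also negative without WT 1, Pxmp2-/- 1 or Pxmp2-/- 2 (-0.028, -0.0044 and -0.0069). Fos (0.63 ± 0.15) and the retinoic acid receptor gene Rara (0.50 ± 0.12) rose adjusted over the list alone, and no gene of the list passed over all probe sets. The progesterone receptor gene Pgr differed by 0.20, the estrogen receptor gene Esr1 by -0.02 and Igf1 by -0.18. Among 29 tested growth factors and proteases of the mammary stroma, 3 fell adjusted over the list alone, and none passed over all probe sets. They were Egfr (-1.11 ± 0.14), the keratinocyte growth factor gene Fgf7 (-0.70 ± 0.13) and the gelatinase gene Mmp2 (-0.77 ± 0.17). Fgf10 differed by 0.05 and Hgf by -0.15. The list as a whole averaged -0.13 (camera adjusted p = 0.445).

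White adipocyte transcripts were among the brightest on the arrays, so that a change in several of them may not show. Array maxima lay between 20504 and 22654, and Fabp4 read 21610 ± 938 in WT and 21138 ± 979 in Pxmp2-/- mice, and Adipoq 16119 ± 847 and 15848 ± 697 (SD, n = 3 each). The dimmest of the 4 tested Fabp4 probe sets read 5930 ± 1587 and 4339 ± 1679 (SD, n = 3 each; limma adjusted p = 0.45). The adipocyte list averaged -0.067 over 19 genes (camera adjusted p = 0.6) and the brown adipocyte list 0.068 over 15 genes (adjusted p = 0.189), with no gene of either passing over all probe sets or adjusted over the list alone. The 11 adipocyte genes with mean intensities under 10252 averaged -0.13 (camera adjusted p = 0.22), 9 of them lower, and the 8 brighter ones 0.016, a division chosen after the data were seen. Without WT 2 the mean of the whole list was -0.043. The glucose transporter gene Slc2a4 differed by -0.22, Itga7 by -0.31, the brown fat regulator gene Prdm16 by -0.40 and Otop1 by 0.44. The brown adipocyte list depended on single arrays, passing without Pxmp2-/- 1 (0.18, adjusted p = 0.023) and without WT 2 (0.13, adjusted p = 0.047), and turning to -0.029 without Pxmp2-/- 2 and -0.0015 without WT 1.

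Endothelial transcripts were lower in Pxmp2-/- mice. The list fell by 0.22 log2 on average over 19 tested genes (camera adjusted p = 5.1e-04), with an adjusted p of 0.51 with an estimated correlation. Adjusted over the list alone 7 genes fell, 12 did not pass and none rose, and none passed over all probe sets. Among the 7 were the transcription factor gene Sox18 (-0.55 ± 0.10), Egfl7 (-0.37 ± 0.09), Erg (-0.37 ± 0.09) and Kdr, a receptor of vascular endothelial growth factor (-0.48 ± 0.13). The fibroblast and extracellular matrix list averaged -0.15 over 21 genes (camera adjusted p = 0.0465), with an adjusted p of 0.64 with an estimated correlation. Adjusted over the list alone 4 of its genes fell and 3 rose, with none past the threshold over all probe sets. The growth factor receptor gene Pdgfra (-1.25 ± 0.27) and the collagen cross-linking enzyme gene Lox (-0.43 ± 0.11) were lower, and Mfap5 (0.61 ± 0.11) and Thy1 (0.60 ± 0.16) higher. This call was lost without WT 2 (-0.082), WT 3 (-0.15), Pxmp2-/- 1 (-0.17) or Pxmp2-/- 3 (-0.1), with adjusted p of 0.37, 0.063, 0.14 and 0.059. It was also lost without chromosome 5 genes, Pdgfra among them (-0.097, adjusted p = 0.11), with the 60th percentile filter (adjusted p = 0.2), with array weights (0.078) and with a pseudocount of 1 (0.05).

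Lists of immune cell markers averaged higher in Pxmp2-/- mice. The macrophage list rose by 0.27 on average over 20 tested genes (camera adjusted p = 1.47e-05), with an adjusted p of 0.64 with an estimated correlation. Adjusted over the list alone 3 genes rose, 17 did not pass and none fell, and none passed over all probe sets. The 3 were Lyz2, from 1313 ± 51.0 to 2380 ± 245 (SD, n = 3 each), the lysosomal protease gene Ctss (0.74 ± 0.16) and Adgre1, which encodes the F4/80 antigen (0.46 ± 0.13). The list level was highest in Pxmp2-/- 1, the array that stood apart on the second component (0.42 above the mean of the 6 arrays, against -0.02 and 0.01), and the shift was 0.13 without that mouse (adjusted p = 0.0049).

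Lymphocyte lists averaged higher as well, with overlapping genotypes for T cells. The B lymphocyte list rose by 0.30 over 10 tested genes (camera adjusted p = 5.1e-04), with an adjusted p of 0.51 with an estimated correlation. The signalling adaptor gene Blnk (0.42 ± 0.10) was the single member to pass adjusted over the list alone, and Cd22 differed by 0.36. The T lymphocyte list rose by 0.30 over 10 genes (adjusted p = 7.23e-03), with an adjusted p of 0.64 with an estimated correlation. None of its genes passed adjusted over the list alone, with Themis at 0.41 and Cd2 at 0.41, and no gene of either list passed over all probe sets. The T level of Pxmp2-/- 3 (-0.22) lay below those of WT 1 (-0.05) and WT 3 (-0.08), with an exact permutation p of 0.4 for the T list. Both lists were highest in Pxmp2-/- 2, at 0.40 for B cells and 0.59 for T cells. Without that mouse the B shift was 0.18 (adjusted p = 0.017) and the T call was lost (0.079, adjusted p = 0.36), as it was without WT 2 (0.22, adjusted p = 0.064), while without Pxmp2-/- 3 the T shift was 0.48. The granulocyte and mast cell list rose by 0.23 over 8 genes (adjusted p = 6.86e-03), with an adjusted p of 0.51 with an estimated correlation and with no gene passing over all probe sets or adjusted over the list alone. The mast cell chymase gene Cma1 differed by 0.50 and Ltf by 0.16. Genotypes overlapped, with a list level of 0.07 in WT 1 and 0.02 in Pxmp2-/- 3. The list's call was lost without WT 2 (0.15, adjusted p = 0.061) and with no level filter (0.064, adjusted p = 0.27). Interferon response genes rose by 0.18 over 23 genes (adjusted p = 9.94e-04), with an adjusted p of 0.64 with an estimated correlation and no member passing either way. Oasl2 differed by 0.57 ± 0.20 and Cxcl10 by 0.67 ± 0.26, the only 2 members with an unadjusted limma p under 0.05. Both lie on chromosome 5, the chromosome of Pxmp2, Oasl2 48 tested genes after it and Cxcl10 84 before it. The list level was 0.38 in Pxmp2-/- 1, which stood apart, and -0.13 and 0.03 in the other Pxmp2-/- mice. In WT mice it was -0.16, -0.11 and 0, so the genotypes overlapped. Without Pxmp2-/- 1 the shift was 0.038 (adjusted p = 0.16), and without Pxmp2-/- 2 it was 0.29.

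Lists on tissue handling and cell division also shifted. Immediate early and heat shock genes, which respond to handling as well as to hormones, rose by 0.17 over 27 genes (camera adjusted p = 1.49e-03), with an adjusted p of 0.51 with an estimated correlation. Adjusted over the list alone 6 rose and 21 did not pass, among the 6 Dusp1 (0.53 ± 0.12), Nr4a1 (0.74 ± 0.17), Fos and Egr3 (0.80 ± 0.22), and none passed over all probe sets. The level was 0.22 in Pxmp2-/- 1, which stood apart, against 0.04 and 0 in the other Pxmp2-/- mice, and without it the shift was 0.10 (adjusted p = 0.026). Cell cycle genes rose by 0.19 over 30 genes (adjusted p = 1.49e-03), with an adjusted p of 0.64 with an estimated correlation. None of its genes passed over all probe sets or adjusted over the list alone, Top2a differing by 0.68 ± 0.30 and Ube2c by 0.62 ± 0.20. That call was lost without WT 1 (0.083, adjusted p = 0.10) and without Pxmp2-/- 1 (0.031, adjusted p = 0.31), the array with the highest level (0.42). The shift was 0.31 without WT 2 (adjusted p = 7.4e-06) and 0.34 without Pxmp2-/- 2 (adjusted p = 2.7e-08). Genotypes overlapped, with a cell cycle level of -0.2 in Pxmp2-/- 2 and 0.14 in WT 2. Peripheral nerve markers rose by 0.38 on average over 9 genes (adjusted p = 6.86e-03), with an adjusted p of 0.51 with an estimated correlation. Their median was 0.23, and the level of WT 1 (0.12) lay above that of Pxmp2-/- 2 (0.05). Mal differed by 1.56 ± 0.54 and varied widely among WT mice (388 ± 371, SD, n = 3). No nerve marker passed over all probe sets or adjusted over the list alone, with the myelin gene Mbp at 0.85 ± 0.30 and Sox10 at 0.41 ± 0.12. Without Pxmp2-/- 3 the nerve call was lost (0.35, adjusted p = 0.059).

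The remaining lists did not pass. Circadian clock genes averaged -0.14 over 15 genes (camera adjusted p = 0.208), with Nfil3 (-0.63 ± 0.14) passing adjusted over the list alone and none over all probe sets. The clock mean was -0.087 without WT 1, -0.085 without Pxmp2-/- 2 and -0.2 without WT 3 (adjusted p = 0.063). Skeletal muscle averaged 0.077 over 10 genes (adjusted p = 0.369), smooth muscle 0.025 over 8 (adjusted p = 0.523) and red blood cell genes -0.062 over 6 (adjusted p = 0.681), with no gene of these passing either way. With no level filter the skeletal muscle list passed (0.19, adjusted p = 0.038). Without single arrays its mean ranged from 0.032 to 0.12 (without Pxmp2-/- 1 or 2), smooth muscle from -0.0061 to 0.059 (without Pxmp2-/- 2 or 1) and red blood cell genes from -0.1 to -0.041 (without Pxmp2-/- 2 or 3). Their smallest p values belonged to Mylpf (0.54), Synpo2 (0.29) and Alas2 (-0.30). Skin and hair genes were too few to test, with 4 above the level filter. In all, 11 of 30 lists passed, 9 higher and 2 lower, and none passed with an estimated correlation. The rotation test fry, which asks whether a list moves one way without comparing it with other genes, called 1 list, peroxisome biogenesis and membrane, which holds Pxmp2.

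**Figure D2:**
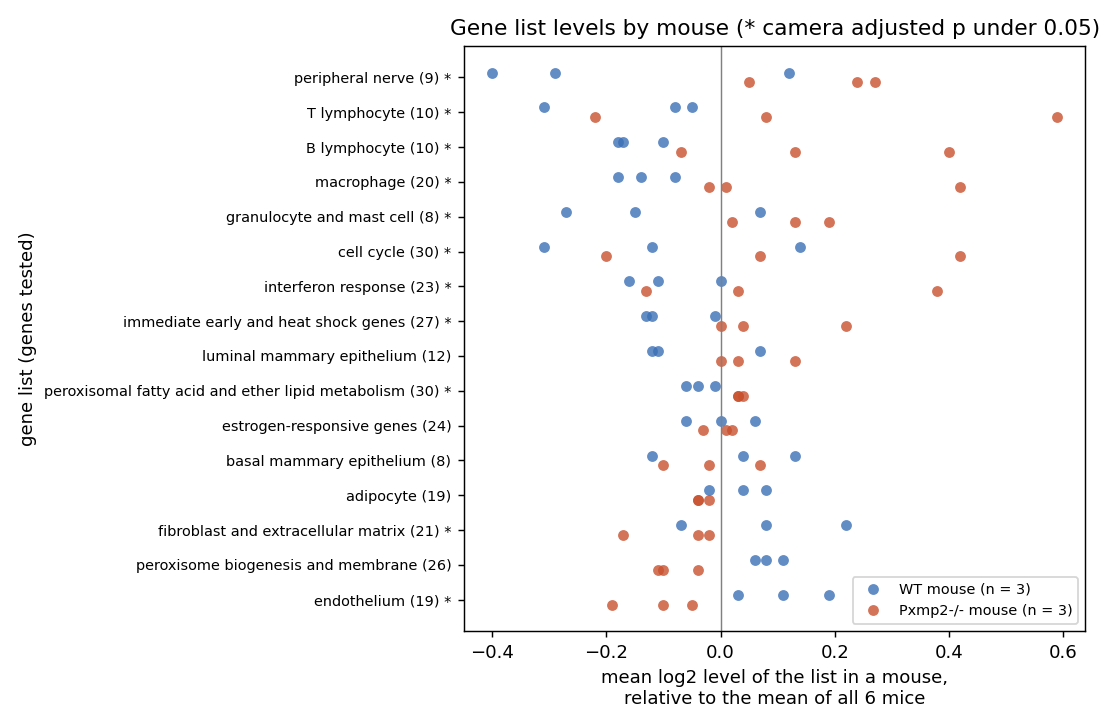
Mean log2 level of 16 gene lists in each mouse (horizontal axis, relative to the mean of all 6 mice), with WT mice in blue and Pxmp2-/- mice in red, and an asterisk at the 11 lists with a camera adjusted p under 0.05. All 3 Pxmp2-/- mice lay below all 3 WT mice for endothelium, and the macrophage level ranged from -0.02 to 0.42 in Pxmp2-/- mice and from -0.18 to -0.08 in WT mice.

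The genes beside Pxmp2 on chromosome 5 were tested as a list of their own, with the gene order of the GRCm38.p6 assembly. Among 11 tested neighbours, 3 passed adjusted over the list alone and none over all probe sets. The DNA polymerase gene Pole, next to Pxmp2, differed by -0.88 ± 0.12, Ankle2 by -0.34 ± 0.09 and the RNA helicase gene Ddx51 by 0.36 ± 0.09, while Golga3 differed by -0.02 and Pus1 by -0.00279. Pole was dim, at 94.4 ± 13.3 in WT and 43.7 ± 5.73 in Pxmp2-/- mice (SD, n = 3 each), the latter under the filter intensity of 59.1. The list averaged -0.12 (camera adjusted p = 0.378). Farther out, and chosen after the data were seen, genes with an unadjusted p under 0.001 were counted by chromosome, with the brightest probe set of each gene and without Pxmp2. Chromosome 5 held 13 among 810 tested genes (1.6%), and the other chromosomes together 48 among 11935 (0.402%). The odds ratio was 4.04 (95% interval 2.00 to 7.61, Fisher's exact test, two-sided, p = 9.5e-05). Of the 13 genes, 9 were higher and 4 lower. They lay from 236 tested genes before Pxmp2 (Cytl1) to 72 after it (Hspb8), the largest differences being those of Atp10d (1.38), Cytl1 (1.35), Ptpn13 (1.19) and Zfp932 (-1.08). Also on chromosome 5, at an unadjusted p of 0.001 or more, were Oasl2, Cxcl10, Kdr, Acads, Acacb, Otop1, Insig1, Acox3 and Pdgfra, among other genes named above. Without chromosome 5 genes, limma called 0 of 25577 probe sets, with a smallest adjusted p of 0.056 and 4222 at an unadjusted p under 0.05. The differences themselves did not change, and taking out the smallest p values shifts the adjustment. H2-Ab1 (1.00, adjusted p = 0.0558), Fst (-1.19, 0.0705), Tmem158 (-0.99, 0.0912) and Clasp2 (0.97, 0.0913) then lay above the threshold, with H2-Ab1 the nearest to it.

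**Figure D3:**
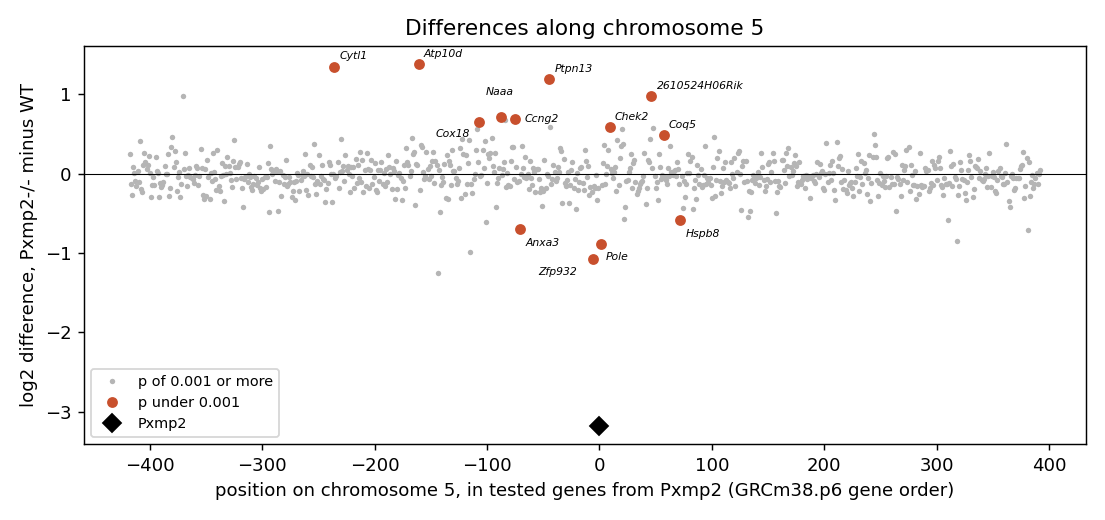
Log2 difference (Pxmp2-/- minus WT) of each tested gene of chromosome 5 against its place in tested genes from Pxmp2, by GRCm38.p6 gene order, with red points for the 13 genes at an unadjusted p under 0.001 and a black diamond for Pxmp2 (-3.18). The red points lie between 236 genes before and 72 genes after Pxmp2, while the tested genes reach 392 after it.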

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

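The alternatives were chosen before the data were examined, except those without chromosome 5 genes, without adipocyte genes near the highest intensities (-0.13), without Pxmp2 in its own list and the scalings applied to the unnamed probe sets. The Pxmp2 difference stayed between -3.26 and -2.99 and past the threshold in all 20 alternatives run on it. The 17 calls were far less stable. The numbers changed, higher and lower were 1, 0 and 1 with no level filter, 34, 18 and 16 with a mean-variance trend, 5, 1 and 4 with one probe set per gene, 6, 3 and 3 with the mean of probe sets per gene, and 31, 11 and 20 at an adjusted p under 0.10. With array weights 26 changed and 16 were lower. All 17 were among the calls made with the trend and with array weights, and 15 were among the 16 calls after quantile normalization. With one probe set per gene, a brighter probe set stood for Hsd17b11 (0.02 against 1.05), Pebp1 (-0.09 against -0.89) and others. With no level filter the folds stayed as they were (H2-Ab1 1.00, limma adjusted p = 0.156). More tests raise the adjusted p, and what else raised it there was not tested. Without chromosome 5 genes limma called 0, 0 and 0, with 4222 probe sets at an unadjusted p under 0.05 and 8 at an adjusted p under 0.10, and the folds of the remaining probe sets stayed as they were. Leaving out single arrays gave 1 to 33 changed, 0 to 15 higher and 1 to 18 lower. The most came without Pxmp2-/- 1 (33), of which 10 were among the 17, and the fewest without WT 3, Pxmp2-/- 2 or Pxmp2-/- 3, where Pxmp2 alone passed. Fewer arrays leave fewer degrees of freedom, and what raised the count without Pxmp2-/- 1 was not tested.

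With the replicate number as a block (replicate block), 1 probe set changed, 0 higher and 1 lower, and 11 lists passed. The deviations of same-numbered arrays correlated at 0.022, 0.044 and -0.12 across probe sets, and not every array correlated best with its own number, so the block costs degrees of freedom without a pairing that the data show.

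The number of lists past the threshold was 7 with the 60th percentile filter, 0 with an estimated correlation (1 at an unadjusted p under 0.05) and 1 with fry, and between 8 and 12 in all other alternatives. The peroxisome biogenesis list passed with fry (-0.17, adjusted p = 0.047; its range over the alternatives was 0.047 to 0.75). The peroxisomal fatty acid list no longer passed with an estimated correlation (0.071), with fry (0.071) or without chromosome 5 genes (0.062), and ranged from 0.061 to 0.086 over the fits without single arrays. Over those fits the luminal list ranged from 0.071 to 0.17, the PPAR list ranged from -0.038 to 0.09 and the basal list from -0.1 to 0.021. With one probe set per gene, Clasp2 (-0.0331), Pip5k1a (-0.0806) and Eif4h (0.00655) turned sign, since a brighter probe set then stands for each. Lists with means near 0 that did not pass turned sign too. They were antioxidant enzymes after quantile normalization (0.023), with the mean of probe sets (0.016) and without single arrays (-0.04 to 0.011), and cholesterol synthesis after quantile normalization (0.0022) and without single arrays (-0.15 to 0.0078). Estrogen-responsive genes did so after median centring (-0.0082), with a pseudocount of 64 (-0.016), with the 60th percentile filter (-0.077), with array weights (-8.5e-05) and without single arrays (-0.028 to 0.029). Red blood cell genes did so without _x_at and _s_at probe sets (0.0073), and, without single arrays, mitochondrial fatty acid oxidation (-0.0051 to 0.061), brown adipocyte (-0.029 to 0.18) and smooth muscle (-0.0061 to 0.059). Some lists gained a call, which were cholesterol synthesis (-0.15) and the prostaglandin pathway (0.082) without WT 3, mitochondrial fatty acid oxidation (0.059) and brown adipocyte (0.18) without Pxmp2-/- 1, brown adipocyte without WT 2 (0.13) and skeletal muscle with no level filter (0.19). The cause was not tested for these. With the cases above included, of 466 values of named genes other than Pxmp2, 318 kept direction and side of the threshold, 107 lost the call, 38 gained one and 3 turned sign. Of 475 values of lists other than the peroxisomal, PPAR, epithelial and white adipocyte ones, 413, 36, 6 and 20 did so. Dim signal limits several lists, with 12 of 33 luminal, 8 of 19 basal, 10 of 27 skeletal muscle and 8 of 20 granulocyte and mast cell genes on the array above the level filter.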

Other observations

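All tests in this part, except the counts over splits of the arrays, were chosen after the results were seen. MHC class II genes, which present antigen on macrophages, dendritic cells and B cells, were higher together in Pxmp2-/- mice. Of 10 listed genes 6 were tested, and their mean log2 difference was 0.57, with a camera p of 2.98e-09 and a p of 0.042 with an estimated correlation. This list was written after H2-Ab1, H2-Aa and H2-Eb1 had been seen among the named genes, so it is not independent evidence. Adjusted over the list alone 5 of the 6 rose, and none of these brightest probe sets passed over all probe sets. H2-Eb1 went from 998 ± 81.7 to 1801 ± 245, H2-DMa from 152 ± 7.07 to 252 ± 27.6 and Cd74 from 4065 ± 595 to 5627 ± 492 (SD, n = 3 each), while H2-DMb2 differed by 0.20. The list level was 0.46, 0.19 and 0.20 in the Pxmp2-/- mice and -0.27, -0.38 and -0.19 in the WT mice (exact permutation p = 0.1, the smallest that 3 against 3 allow).

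The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 17 changed probe sets and the highest other split 0, so 1 split gave as many. For gene lists past the threshold the real split gave 11 and the highest other 12, so 2 splits gave as many.

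Genes with an unadjusted p under 0.001 lay together on chromosome 5. Random placement of these 61 genes argues against chance, since none of 10000 placements put as many as the observed 11 into a window of 201 neighbouring genes (permutation p = 1.0e-04, the smallest they can give, with 9 the most by chance and 4 the most on any other chromosome). The odds ratio of 4.04 for chromosome 5 restates the excess that prompted it. It therefore cannot weigh separately against a response that ignores position. A candidate explanation is DNA of the strain used for gene targeting, carried along with the Pxmp2 locus, since within chromosome 5 such genes were more frequent within 100 tested genes of Pxmp2 (10 of 200) than farther away (3 of 610), with an odds ratio of 10.6 (95% interval 2.70 to 60.6, Fisher's exact test, two-sided), and of 4.6 (1.16 to 16.3) for a window of 50 genes and 12.6 (1.85 to 541) for 200. Base differences under single probe sets cannot be told apart from changed transcript levels, because 7 other probe sets were tested, for 5 of the 13 genes, and 57.1% of them (4 of 7) moved the same way with p under 0.05. For the named genes past the threshold on this chromosome 2 of 13 other probe sets did (15.4%, 95% interval 1.92 to 45.4). For those elsewhere 3 of 5 did (60%, 14.7 to 94.7). The probe set compared was the one with the smallest p of its gene, which favours disagreement of the others. Local effects of the disrupted locus on its neighbours, and the strain of the targeted cells, which is not given in the sources used here, stay open and were not tested.

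Macrophage and antigen presentation genes averaged higher in Pxmp2-/- mice, but the macrophage call was lost with an estimated correlation (adjusted p = 0.64), and Pxmp2-/- 1, the array that stood apart, carried much of its shift (level 0.42 against -0.02 and 0.01, shift 0.13 without it). A smaller share of the main tissue that raised all other cell types alike would move the endothelial and macrophage scores together. They parted by -0.49 ± 0.12 (SE, exact permutation p = 0.1, the smallest that 3 against 3 allow). The gap was -0.46 in Pxmp2-/- 1 and -0.08 and -0.195 in the other Pxmp2-/- mice. Both lists were already known to move in opposite directions when they were chosen, so this gap cannot decide on that form. If endothelial cells are lost with the main tissue, the scores would part as seen, so a smaller share of the main tissue stays open in this form too. The fibroblast and adipocyte lists averaged lower too (-0.15 and -0.067). More lymph node in the dissected pads cannot be told apart, because the MHC class II score minus the lymphocyte score differed by 0.26 ± 0.22 (SE) between genotypes, at 0.355, -0.305 and 0.344 in the Pxmp2-/- mice and -0.195, -0.136 and -0.063 in the WT mice. A change in the immune cells of the fat pad with genotype may also account for it and was not tested apart from these scores.

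Probe sets with no listed gene symbol were mostly lower in Pxmp2-/- mice, 279 against 50 at an unadjusted p under 0.01 (84.8% lower), where the share lower was 57.8% for probe sets with a single symbol and 35.7% for those with several (5 lower, 9 higher). Array scaling as the whole cause is argued against by quantile normalization, after which 80.1% of unlisted probe sets were lower, against 44.2% of those with a single symbol, and median centring gave 88.0% and 68.1%. Less unspliced or partly degraded RNA in the Pxmp2-/- samples could lower such probe sets, and stays open, since within genes the dimmer probe sets stood 0.035 ± 0.021 (SE) higher against the brightest in Pxmp2-/- mice, which lies within 2 SE of 0. A biological explanation by genotype was not tested.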
